A study of Homo sapiens with 4 samples.

How the data were processed

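RNA from 4 cultures of endocrine-resistant breast cancer cells was sequenced, 1 library for each combination of cell line (LCC2 or LCC9) and lentiviral vector (empty control or ESRP1 knockdown). Total RNA was extracted with an Ambion kit from cells in charcoal-stripped medium and sequenced as paired ends, per the labels' protocols; read length, strand, depth and whether the knockdown cultures were single clones or pools are not given in the sources used here. Bowtie, Cufflinks and the hg19 build are named in the submitters' processing notes, without versions or options. Each deposited file is a Cufflinks transcript table with the FPKM (fragments per kilobase of transcript, scaled to the mapped fragments), its 95% interval and the coverage of every annotated transcript, per the file headers and attributes. The deposited FPKM values cover 214292 Ensembl transcripts of 63654 gene IDs in each library. Coordinates are printed as the files give them, on hg19.

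Gene symbols came from a table of Ensembl IDs and symbols, in which 52166 of the 63654 IDs were found and 39694 had a symbol. Older symbols in the gene lists were matched through the synonyms of the RefSeq table of GRCh38.p14, of which no coordinate was used. This matching replaced an earlier one, under which some list members had been missed, after the first list results had been seen. The FPKM of a gene is the sum over its transcripts, and all ratios are log2 of FPKM plus a pseudocount of 1, which understates the change of low genes. The 14979 genes with FPKM of at least 1 in a library were tested. Genes were eligible for naming where they also had a symbol, a transcript of at least 300 nt and no mitochondrial origin, which left 13086. Transcripts under 300 nt took 69.9% of the summed FPKM in the LCC2 control, 57.5% in the LCC2 knockdown, 43.9% in the LCC9 control and 51.0% in the LCC9 knockdown, and Cufflinks values of such short transcripts are unstable.

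Depth was read from the ratio of Cufflinks coverage to FPKM, which is proportional to the mapped fragments times the bases counted for each. Its median was 5.44 and 5.45 in the LCC2 control and knockdown libraries and 10.9 and 10.8 in the LCC9 control and knockdown libraries, so that this measure differs between the lines. Intervals and standard errors derived from Cufflinks cover counting and isoform assignment in 1 library, not the spread between cultures.

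With 1 library per group, no test exists within a line. Genes at least 2-fold higher or lower were counted in each line and compared with n1 × n2 / N, the overlap of independent lists. The only test was limma 3.58.1 in R 4.3.3 on all 4 libraries, with line and vector as additive terms, a trend in the moderated variance and Benjamini-Hochberg adjustment at 0.05. It has 1 residual degree of freedom, and its error is the disagreement between the lines, so its p-values treat the lines as the replicates. On simulated data for the knockdown comparison (14979 genes, 200 of them changed, spread drawn from the fitted prior), 2% of genes with a log2 change of 1 were recovered, 54% with 2, 96% with 3 and 100% with 4, and 3.82% of calls were false. With the moderated spread of each gene instead, 12%, 96%, 100% and 100% were recovered and 13.5% of calls were false. The changed genes were drawn only from those with a mean log2 value above 3, and noise was drawn independently for each gene. Recovery therefore does not cover low genes. Neither rate covers genes whose disagreement between the lines is shared.

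The 30 gene lists were fixed before the data were examined; the fatty acid, cholesterol and serine lists were chosen knowing that the study's own publication concerns metabolic genes. Lists with at least 3 tested members (26) were tested with camera at a preset correlation of 0.01, with an estimated correlation beside it. Within a line, a list's median was placed among 10000 random lists of the same size matched on mean expression. With the estimated correlation, which rests on 1 residual degree of freedom, no list was called.

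A cassette exon is an annotated exon whose flanking exons are also joined directly in another transcript of the gene. Inclusion is the FPKM of transcripts with the exon as a percent of the FPKM of both kinds. Of 36981 such exons, 18004 had a summed FPKM of at least 1 in all 4 libraries. Changes of at least 20 percentage points the same way in both lines were counted beside those going opposite ways, and exons of 36 ESRP targets from the literature were compared with 10000 random exon sets matched on gene level. Exons of these sets were drawn singly, so exons of the same gene, which share transcripts, were treated as independent. These functions were tested on simulated data.

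Genes named in the text were chosen by a rule fixed before the data were examined. It took ESRP1 and ESRP2, the 10 highest and 10 lowest by the smaller ratio of both lines (FPKM of at least 5 in a library of each line), the 5 highest and 5 lowest in each line, the 10 highest and 10 lowest between the lines, 5 genes in each opposite direction, up to 4 members of each list with the largest mean ratio, ESRP target exons moving at least 10 points the same way in both lines, and the 10 exons with the largest smaller change. Genes outside this rule are marked where named, and some genes and exons within it are not reported here. Alternatives were other pseudocounts (0.1 and 5), no filter or FPKM of at least 5, rescaling to a common sum, median-of-ratios scaling, no variance trend, no term for the other factor, transcripts of at least 300 nt alone, other exon minimums, and transcripts whose Cufflinks interval lay above 0. Strand is not stated, so antisense genes and their partners cannot be told apart, and genes with close copies or pseudogenes may share reads. The share of target exons moving at least 10 points was chosen after the values were seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used.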

Results

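Gene expression was measured by RNA sequencing in LCC2 and LCC9, breast cancer lines derived from MCF-7 that resist endocrine therapy. LCC2 is resistant to tamoxifen, and LCC9 to fulvestrant and tamoxifen. Each line carried either an empty lentiviral vector or a vector against ESRP1, an epithelial regulator of alternative splicing, giving 4 groups of 1 library each. No value below therefore has a replicate of its own. Between 13138 and 13641 genes reached an FPKM of 1 in a library. Coverage per FPKM, a measure of depth, was 5.44 and 5.45 in the LCC2 control and knockdown and 10.9 and 10.8 in the LCC9 control and knockdown, so this measure was alike within a line and not between the lines.

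The targeted gene was measured first, as a check of the labels. ESRP1 (ENSG00000104413, hg19 chromosome 8, 95653302 to 95719694) had an FPKM of 52.1 in the LCC2 control, with a Cufflinks half-width of 3.15, and 7.23 with a half-width of 1.41 in the LCC2 knockdown, leaving 13.9%. In LCC9 it was 63.5 in the control and 11.1 in the knockdown, leaving 17.5%. The limma estimate over both lines was a log2 change of -2.55 with a standard error of 0.35, and its adjusted p of 0.0557 missed the threshold. ESRP2, the paralogue with overlapping targets, was at 13.1 and 13.0 in the LCC2 control and knockdown and at 8.07 and 10.2 in LCC9.

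The first comparison asked which genes differed between knockdown and control in both lines. Higher in both were TNFRSF11B (osteoprotegerin, a decoy receptor of the RANK ligand), at 2.89 in the control and 118 in the knockdown of LCC2 and at 12.7 and 157 in LCC9, and SOCS3, a feedback inhibitor of cytokine signalling, at 5.97 and 85.2 in LCC2 and 2.36 and 25.4 in LCC9. MGP, a matrix protein that inhibits calcification, was at 20.8 and 181 in LCC2 and 2.66 and 22 in LCC9. NPY1R, a neuropeptide Y receptor, was lower in both, at 76.2 and 8.49 in LCC2 and 60.1 and 4.69 in LCC9. These 4 were the named genes of at least 300 nt that limma called: TNFRSF11B rose by 4.23 on the log2 scale (SE 0.42, adjusted p = 0.00729), SOCS3 rose by 3.30 (SE 0.36, adjusted p = 0.0123), MGP rose by 2.85 (SE 0.35, adjusted p = 0.0268) and NPY1R fell by 3.22 (SE 0.35, adjusted p = 0.0123), each in the same direction in both lines.

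The rest of the genes highest in both lines were the flippase gene ATP8A2, the interferon-induced IFIT1 and IFI6, RHOBTB3, the secretory granule gene CHGA, the scaffold gene PDZK1 and the imprinted non-coding RNA H19. CHGA had log2 ratios of 6.31 in LCC2 and 1.94 in LCC9, PDZK1 4.71 and 1.9, RHOBTB3 2.93 and 2.01, ATP8A2 2.46 and 2.43, and H19 1.862 and 1.961. Lowest beside NPY1R and ESRP1 were S100P, a calcium-binding protein (-2.45 in LCC2 and -1.88 in LCC9), HPGD, which degrades prostaglandins (-2.42 and -1.82), the metalloprotease gene ADAMTS19 (-1.67 and -2.74), the transcription factor gene BHLHE40 (-1.47 and -1.48), SAP30 of the SIN3 corepressor (-1.71 and -1.25) and SNX25 (-1.35 and -1.24). The pseudogene NUS1P2 (-1.52 and -1.84) and the antisense gene DGUOK-AS1 (-1.35 and -1.89) were also among them, and their values are uncertain because reads may belong to the parent gene or the opposite strand. None of these was called. Over the 14979 genes, limma called 9, of which 6 rose and 3 fell, and 5 of the 9 were short non-coding RNAs under 300 nt; 619 genes had an unadjusted p under 0.05. No gene was called when any of the 4 libraries was left out, which also needed the term for line to be dropped. Dropping that term alone left 4 calls, and median-of-ratios scaling left 4 calls, 2 in each direction.

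**Figure D1:**
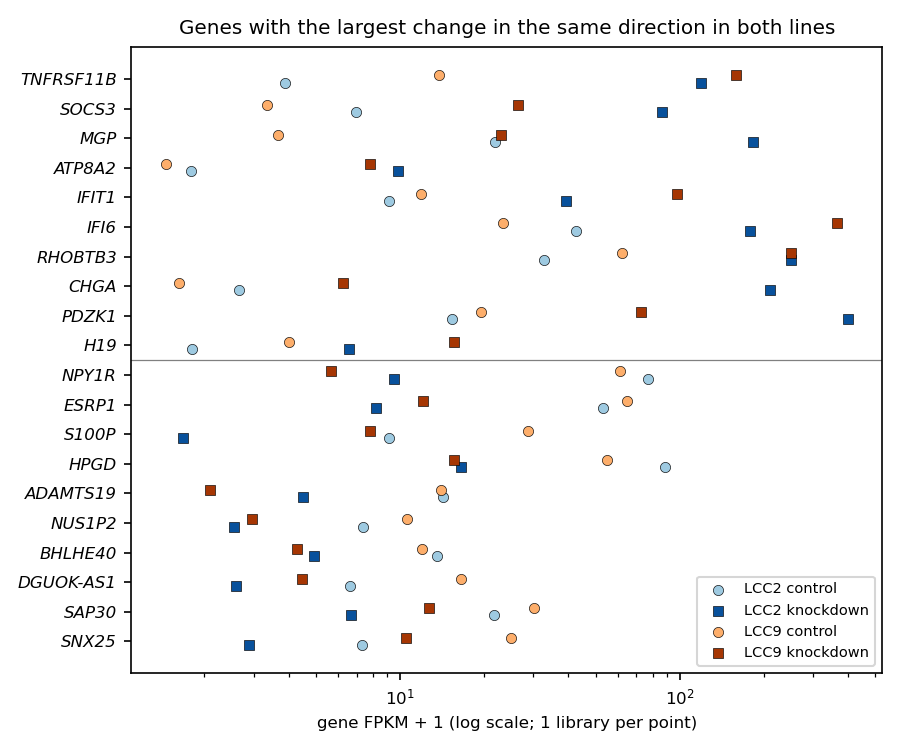
FPKM plus 1 (log axis) of the 10 genes highest and the 10 lowest by the smaller log2 ratio of both lines; each point is 1 library, circles are controls, squares are knockdowns, and there are no error bars because each group has 1 library. ESRP1 is lower in both knockdowns, at 7.23 against 52.1 in LCC2 and 11.1 against 63.5 in LCC9, and TNFRSF11B has the largest smaller ratio among the higher genes.

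By size alone, 126 genes differed at least 2-fold the same way in both lines. Of these, 94 were higher, against 39.7 expected of independent lists, and 32 were lower, against 24.9. Genes going opposite ways outnumbered them: 164 were lower in LCC2 and higher in LCC9, against 29.0 expected, and 57 were higher in LCC2 and lower in LCC9, against 34.1. Across genes, which are not independent replicates, the Pearson correlation of the ratios in both lines was -0.078. The count of 126 was 362 with a pseudocount of 0.1 and 39 with a pseudocount of 5.

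**Figure D2:**
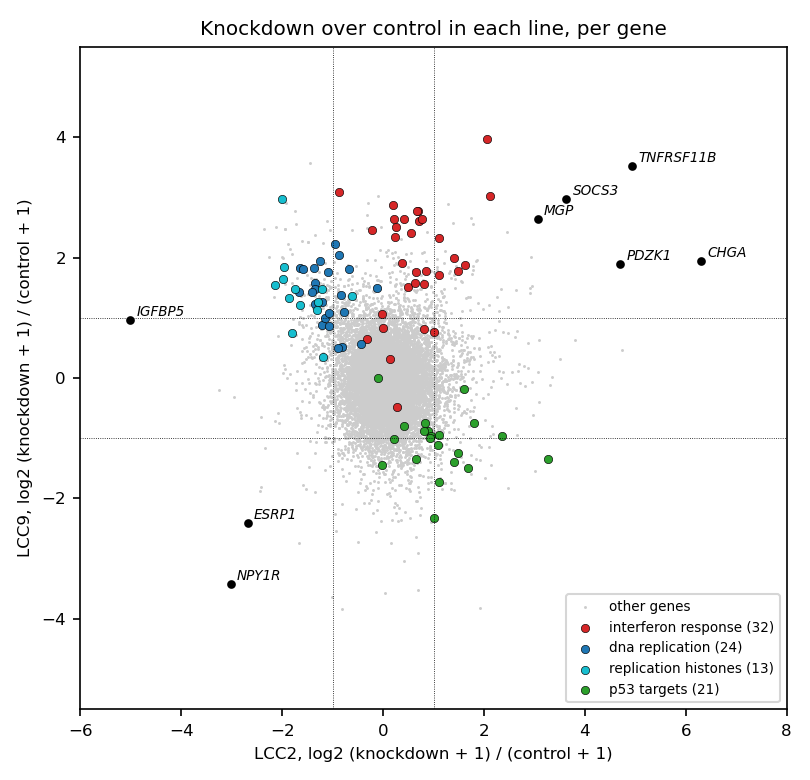
Log2 ratio of knockdown over control (FPKM plus 1) in LCC2 (horizontal) and LCC9 (vertical) for genes with a symbol and at least 300 nt; dotted lines mark 2-fold, and numbers in the key are the tested members of each list. Interferon genes lie mostly in the upper right, while DNA replication and histone genes lie upper left and p53 targets lower right.

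Among the gene lists, the interferon response rose with the knockdown (mean log2 change 1.29, camera adjusted p = 4.6e-32; adjusted p = 0.813 with an estimated correlation). Of its 32 tested members, 26 were higher in both lines and 0 lower in both, and 7 were at least 2-fold higher in both. IFI6 went from 41.5 to 177 in LCC2 and from 22.3 to 364 in LCC9, IFIT1 from 8.11 to 38.3 and from 10.9 to 96.4, ISG15, a ubiquitin-like modifier, from 93.0 to 291 and from 123 to 459, and OAS1, an antiviral synthetase, from 4.24 to 7.45 and from 2.46 to 22.6. The list's median was 0.65 in LCC2 and 1.94 in LCC9, at percentile 100 of matched random lists in both. limma called 0 members over all genes and 24, all higher, adjusted over the list alone. Antigen presentation genes rose with it (16 tested, mean 0.50, adjusted p = 0.000101; 0.813 is the adjusted p with an estimated correlation). The median was 0.49 in LCC9 (percentile 99.9) but 0.22 in LCC2 (percentile 85.0), inside the range of random lists. The median FPKM was 4.22 in the LCC9 control, against 9.39 in the LCC2 control, 14.0 in the LCC2 knockdown and 12.2 in the LCC9 knockdown. Here 10 members were higher in both lines and 0 lower, 0 were called over all genes and 3 adjusted over the list alone. HLA-F went from 3.71 to 10.7 and from 2.42 to 10.5. HLA genes are alike and polymorphic, so how reads were split among them is uncertain.

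Genes of the estrogen response also rose (30 tested, mean 0.47, adjusted p = 4.16e-05; adjusted p = 0.813 with an estimated correlation). Of these, 14 were higher in both lines and 2 lower in both, 0 were called over all genes and 1 adjusted over the list alone. PDZK1 went from 14.3 to 398 in LCC2 and from 18.5 to 71.8 in LCC9. The cadherin gene CELSR2 went from 6.53 to 16.6 and from 2.42 to 6.0. AGR2, a disulfide isomerase of secretory cells, was at 15.7 and 129 in LCC2 but at 23.8 and 22.7 in LCC9, and the EGFR ligand gene AREG was lower in both lines, with ratios of -2.07 and -0.74. Mesenchymal genes rose as a list (13 tested of 33, mean 0.34, adjusted p = 0.0294; adjusted p = 0.813 with an estimated correlation), with 8 members higher in both lines, 1 lower in both, and 0 called in either adjustment. Within a line its medians of 0.37 in LCC2 (percentile 94.2) and 0.15 in LCC9 (percentile 81.9) lay inside the range of random lists. The collagen gene COL6A1 had ratios of 1.20 and 0.76 and COL6A2 0.36 and 1.48, at FPKM of at most 3.75, whereas the intermediate filament gene VIM went from 15 to 4.69 in LCC2 and from 10.5 to 10.3 in LCC9. The NRF2 and oxidoreductase list fell (20 tested, mean -0.27, adjusted p = 0.0294; adjusted p = 0.813 with an estimated correlation), with 11 lower in both, 3 higher in both and 0 called in either adjustment. Its median was low in LCC2 (-0.21, percentile 2.31) and not in LCC9 (-0.09, percentile 45.5). TXNRD1, thioredoxin reductase, went from 165 to 60.1 and from 295 to 143.

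The ATF4 stress list fell in the fit of both lines (23 tested, mean -0.55, adjusted p = 1.84e-05; adjusted p = 0.813 with an estimated correlation), and this came from LCC9. In LCC9, 15 members were at least 2-fold lower and the median was -1.34 (percentile 0), while in LCC2 3 were at least 2-fold higher and the median was 0.30 (percentile 98.4). The stress regulator NUPR1 was at 89.4 in the LCC9 control and 5.34 in the LCC9 knockdown, the transcription factor gene DDIT3 at 94.4 and 7.32, ATF3 at 15.7 and 2.21, and the cystine transporter gene SLC7A11 at 20.03 and 2.19. The LCC9 control stood apart from the other libraries: its median FPKM over the list was 45.9, against 10.4 in the LCC2 control, 15.7 in the LCC2 knockdown and 10.8 in the LCC9 knockdown. None of the 23 was called in either adjustment.

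Cell cycle genes went opposite ways in the lines. Of 24 DNA replication genes, 15 were at least 2-fold lower in the LCC2 knockdown and 18 at least 2-fold higher in the LCC9 knockdown, with medians of -1.13 (percentile 0) and 1.43 (percentile 100). MCM3 of the replicative helicase was at 66.2 and 40.8 in LCC2 and 17.1 and 62.5 in LCC9, CDC6 at 22.9 and 12.1 and at 4.25 and 20.6. The cyclin gene CCNE2 was at 35.9 and 17.9 and at 6.81 and 35.4. Of 30 mitosis genes, 15 were at least 2-fold lower in LCC2 and 16 at least 2-fold higher in LCC9, with medians of -1.0 and 1.03. PLK1, a mitotic kinase, went from 28.6 to 9.17 in LCC2 and from 7.68 to 15 in LCC9, and MYBL2 from 38.6 to 31.0 and from 3.47 to 32.5. Of 13 replication histone genes, 12 were at least 2-fold lower in LCC2 and 11 at least 2-fold higher in LCC9, with medians of -1.75 and 1.36, although reads of these similar genes may be shared. The p53 targets did the reverse, with 11 of 21 at least 2-fold higher in LCC2 and 10 at least 2-fold lower in LCC9 (medians 1.02 and -0.99). CDKN1A, the cell cycle inhibitor p21, was at 11.8 and 122 in LCC2 and 103 and 40.2 in LCC9, and TP53INP1 at 3.17 and 20.3 and at 17.3 and 8.37. In the fit of both lines, camera gave adjusted p = 0.568 for DNA replication, 0.879 for mitosis, 0.6135 for histones and 0.854 for p53 targets.

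Of the metabolic lists, camera called none in the fit of both lines. In LCC9, fatty acid synthesis (percentile 99.9), cholesterol synthesis (99.9), glycolysis (100) and serine and one-carbon genes (0.105) had medians outside the range of random lists. In LCC2, cholesterol synthesis (percentile 2.07) and glycolysis (1.12) lay below that range, and fatty acid synthesis (19.85) and serine and one-carbon genes (12.29) inside it. Fatty acid oxidation and oxidative phosphorylation lay inside it in both lines. Cholesterol synthesis had medians of -0.18 in LCC2 and 0.29 in LCC9 (adjusted p = 0.3955 by camera), fatty acid synthesis -0.03 and 0.36 (0.0862), glycolysis -0.25 and 0.57 (0.879), fatty acid oxidation 0.14 and -0.14 (0.879), nuclear oxidative phosphorylation genes -0.05 and -0.32 (0.0607) and serine and one-carbon genes -0.13 and -0.64 (0.0607). After median-of-ratios scaling the last pair passed the threshold, with adjusted p of 0.0424 and 0.0477, and 0.875 for both with an estimated correlation. SCD5, a fatty acid desaturase, was higher in both lines (4.17 and 16.7 in LCC2, 3.42 and 15.1 in LCC9) and was called when adjusted over the list alone, and FDFT1, squalene synthase, was at 61.9 and 67.2 in LCC2 and 49.4 and 131 in LCC9. PHGDH, the first enzyme of serine synthesis, was at 39.2 and 42.3 in LCC2 and at 163 and 42.8 in LCC9, the LCC9 control again standing apart, and HK2, a hexokinase, was lower in both lines, at 8.97 and 2.68 and at 5.32 and 3.01.

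Among the remaining lists, luminal identity had medians of 0.19 and 0.28 (adjusted p = 0.122), with KRT19 at 1735 and 3646 in LCC2 and 584 and 2027 in LCC9, and ESR1, the estrogen receptor, at 49.3 and 79.1 and at 18.8 and 39.1. Growth factor receptors had medians of 0.07 and 0.30 (0.0862), with FGFR3 at 6.64 and 15 and at 2.08 and 10.1. Medians were 0.13 and 0.07 for epithelial junctions (0.384), -0.06 and 0.41 for basal epithelial genes (0.158), 0.45 and -0.10 for immediate early genes (0.736), 0.16 and 0.12 for NF-kB genes (0.830), -0.24 and 0.25 for hypoxia (0.839), 0.03 and -0.11 for the unfolded protein response (0.830), 0.00 and -0.29 for ribosomal proteins (0.112), and -0.19 and -0.02 for splicing regulators (0.270), in which ESRP1 was the only one of 26 members at least 2-fold lower in both lines. After median-of-ratios scaling, the median of the unfolded protein response in LCC2, that of ribosomal proteins in LCC2 and that of splicing regulators in LCC9 changed sign, as did the small ratios of AGR2 and VIM in LCC9. For fatty acid oxidation, hypoxia and p53 targets, the mean and median over both lines differed in sign. Of markers of other cell types, 1 of 12 markers of blood cells (HBA1, a globin gene of red cells, at most 4.76, and none of the leukocyte markers), 1 of 10 fibroblast markers (COL1A1, at most 5.80) and 2 of 9 endothelial and adipocyte markers (CD36 and PLIN4) reached an FPKM of 1. The 13 mitochondrially encoded genes were listed at 0 in all 4 libraries.

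**Figure D3:**
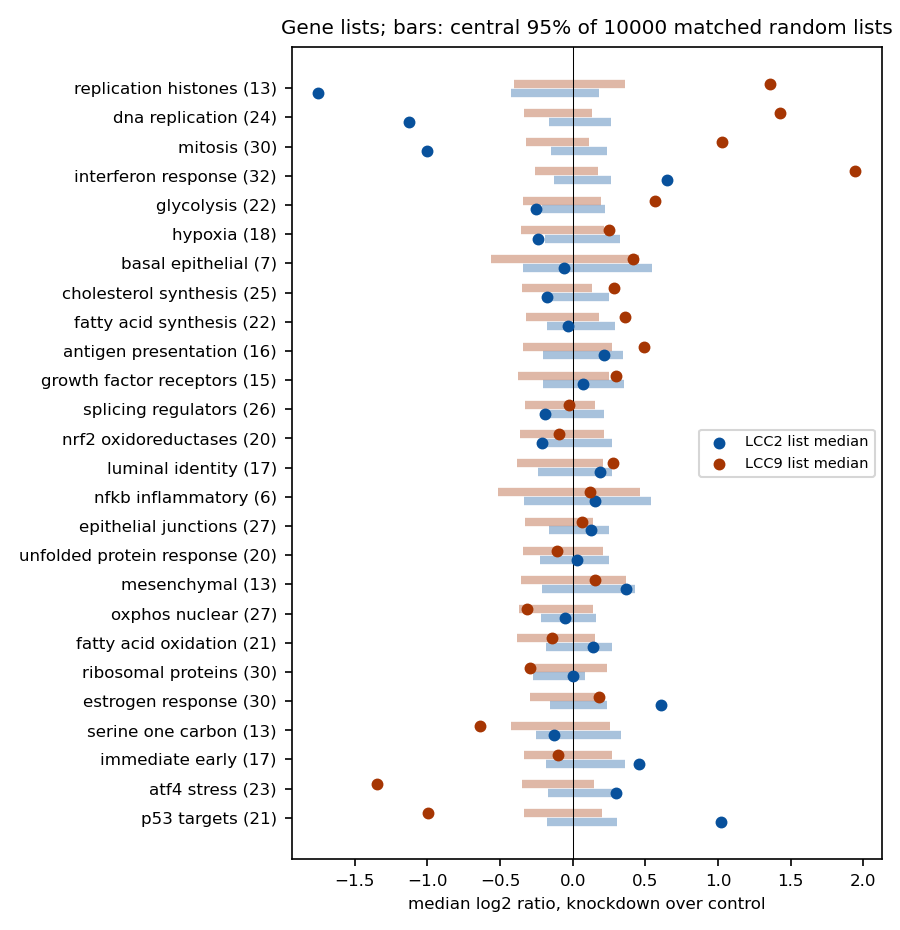
Median log2 ratio of knockdown over control for each gene list in LCC2 (blue) and LCC9 (brown), with the number of tested genes in brackets; bars span the central 95% of 10000 random lists matched on size and mean expression and are not errors of replicates. The interferon response lies to the right in both lines, and histones, DNA replication, mitosis and p53 targets lie on opposite sides of 0.

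Within LCC2, 1266 of 14979 genes differed at least 2-fold, 732 higher and 534 lower. The highest beyond those named above were CYP26B1, which degrades retinoic acid (0.092 in the control and 28.1 in the knockdown), APBB2 (2.12 and 42.9), PHLDA1 (0.706 and 18.4), the calcitonin receptor gene CALCR (0.429 and 13.6) and the readthrough locus DNAJC25-GNG10 (0.169 and 10.6), whose reads may belong to its component genes. The lowest beyond those named above were IGFBP5, a binding protein of insulin-like growth factors (70.2 and 1.21), MIR497HG (22 with a half-width of 46.6, so not distinguishable from 0, and 1.41), the cytokine gene IL20 (57.8 and 6.55), the actin-severing SCIN (14.7 and 1.91) and the linker histone gene H1-3 (477 and 91.7). Of the 5 lower genes, IGFBP5 and H1-3 were higher in the LCC9 knockdown than in its control, with log2 ratios of 0.96 and 2.48. No test was possible within the line, and the count was 2365 with a pseudocount of 0.1 and 445 with a pseudocount of 5.

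Within LCC9, 1511 genes differed at least 2-fold, 813 higher and 698 lower. Highest beyond those named above were TEX19 (0.978 in the control and 22.6 in the knockdown), the interferon-induced IFI27 (83.8 and 718), the growth factor gene BMP7 (21.9 and 186) and the histone genes H1-5 (99.8 and 789) and H3C12 (24.8 and 193). Lowest were NUPR1, the cytochrome P450 gene CYP1A1 (16.7 and 0.256), the glucocorticoid-induced TSC22D3 (82.6 and 5.72), the cytokine gene TNFSF15 (14.4 and 0.295) and DDIT3. IFI27 was lower in the LCC2 knockdown, at 77 in the control and 41.6 in the knockdown. The count was 2639 with a pseudocount of 0.1 and 594 with a pseudocount of 5.

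The second comparison set LCC9 against LCC2. CYBA, a subunit of the NADPH oxidase, was at 0.248 in the LCC2 control and 0.411 in the LCC2 knockdown and at 40.5 and 77.4 in LCC9. The Wnt inhibitor gene DKK1 was at 24.3 and 14.2 in LCC2 and 331 and 99.99 in LCC9, SCIN at 14.7 and 1.91 and at 112 and 71.5, and the fatty acid transporter gene CD36 at 0.291 and 0.204 and at 21.9 and 5.94. COX7B2, ANGPT1, LPP, TRGC1, TES and SH3BGRL were also higher in LCC9, and all 10 were called by limma, with log2 differences from 2.36 for TRGC1 (SE 0.34, adjusted p = 0.0307) to 5.43 for CYBA (SE 0.37, adjusted p = 0.000325). Lower in LCC9 and called were SMIM22 (log2 difference -3.53, SE 0.44, adjusted p = 0.0115), GSTP1, a glutathione transferase (-3.05, SE 0.43, adjusted p = 0.0257), MGP (-2.78, SE 0.35, adjusted p = 0.0130) and TIMP1, a metalloprotease inhibitor (-2.45, SE 0.36, adjusted p = 0.0307). The estrogen-induced TFF1 was at 920 and 1591 in LCC2 and 216 and 230 in LCC9 but missed the threshold (adjusted p = 0.0758), as did LFNG, NR5A2, COL12A1, RERG and TM4SF1.

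limma called 35 genes between the lines, 18 higher and 17 lower in LCC9. Of these, 15 had a symbol and at least 300 nt, 11 higher and 4 lower, and 13 were shorter than 300 nt. The higher ones include TGFB2, named outside the rule after its values were seen. The median log2 difference over the 14979 genes was 0.16 and went to -0.03 with median-of-ratios scaling, which called 10 genes, 4 higher and 6 lower; no gene was called when any of the 4 libraries was left out, which also needed the term for vector to be dropped, and dropping that term alone left 6 calls. Against the other genes, the estrogen response was lower in LCC9 (mean -0.64, camera adjusted p = 1.27e-08), as were luminal identity (-0.41, adjusted p = 0.000365), DNA replication (-0.44, adjusted p = 0.000365), antigen presentation (-0.33, adjusted p = 0.00248) and the mesenchymal list (-0.11, adjusted p = 0.0489). Higher in LCC9 were p53 targets (0.65, adjusted p = 0.0154), the ATF4 stress list (0.68, adjusted p = 0.0109), the interferon response (0.56, adjusted p = 0.0109), the NRF2 list (0.47, adjusted p = 0.0489) and nuclear oxidative phosphorylation genes (0.40, adjusted p = 0.0489). With an estimated correlation, adjusted p = 0.832 for each of these 10 lists. The antigen presentation call came from the control pair, with a median of -0.61 (percentile 0.02) against -0.06 (percentile 13.8) in the knockdown pair. The interferon call came from the knockdown pair, with a median of 1.04 (percentile 100) against 0.05 (percentile 14.8) in the control pair. DNA replication, p53 targets and the ATF4 list had opposite signs in the control and knockdown pairs, with medians of -1.65 and 0.75, 1.74 and -0.47, and 1.39 and -0.17. The median of oxidative phosphorylation genes lay inside the range of random lists in both pairs, at percentile 80.8 for controls and 38.2 for knockdowns. Genes of that expression level were therefore as high in LCC9. The NRF2 and mesenchymal medians lay inside it in the control pair (percentiles 73.5 and 3.34) and outside it in the knockdown pair (98.0 and 0.79). The mesenchymal, NRF2 and oxidative phosphorylation calls ended with median-of-ratios scaling, at adjusted p of 0.0609, 0.0532 and 0.0721, and with a pseudocount of 0.1, at 0.0733, 0.0625 and 0.0662.

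Because ESRP1 regulates splicing, inclusion of annotated cassette exons was compared from the isoform FPKM. Among exons of known ESRP targets, 14 exons of 11 genes moved at least 10 percentage points the same way in both lines. Inclusion of the 93 nt exon of the kinase gene SLK (chromosome 10, 105770574 to 105770666) was 83.2% in the control and 29.2% in the knockdown of LCC2 and 58.4% and 43.9% in LCC9. The 48 nt exon of UAP1 (chromosome 1, 162562525 to 162562572) was at 75.1% and 42.8% in LCC2 and 61.6% and 37.2% in LCC9, and the 72 nt exon of ADAM15 (chromosome 1, 155034380 to 155034451) at 22.4% and 2.9% and at 29.0% and 5.6%. A 51 nt form of the same UAP1 exon, which starts 3 nt earlier and is counted separately among the 14, differed by -18.2 and -14.6 points. Also lower were exons of ITGA6 (-17.2 and -21.1 points), DNM2 (-18.7 and -14.6 points for 1 exon of 12 nt, -15.7 and -12.4 for another), the p120 catenin gene CTNND1 (-15.2 and -13.5) and RALGPS2 (-13.2 and -16.8). Higher were the 240 nt exon of the tight junction gene TJP1 (31.9% and 53% in LCC2, 37.3% and 52.2% in LCC9) and the 36 nt exon of MAGI1 (10.9 and 14.6 points). Standard errors from the Cufflinks intervals were 2.37 and 0.895 points for the changes of SLK, 4.95 and 3.49 for the 48 nt exon of UAP1, and 7.06 and 3.7 for ITGA6. For MAGI1 they were 7.61 and 6.10, so its change in LCC2 was not detectable at this depth.

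**Figure D4:**
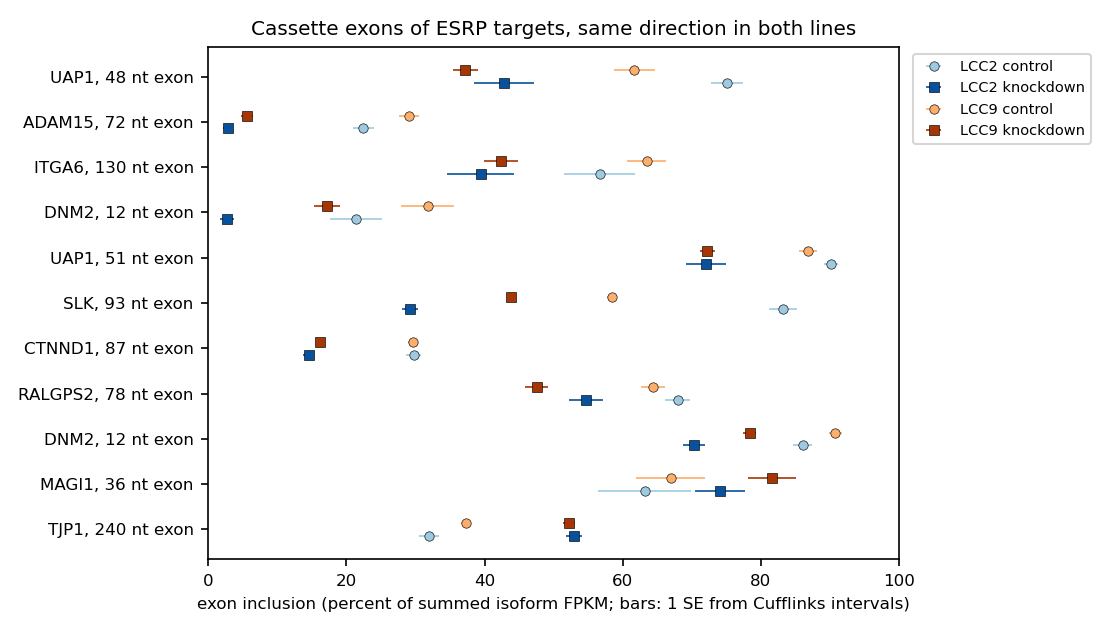
Inclusion (percent of summed isoform FPKM) of 11 of the 14 exons of ESRP targets that moved at least 10 points the same way in both lines; circles are controls, squares knockdowns, and bars are 1 standard error from the Cufflinks intervals of a single library. In 9 exons both knockdowns lie to the left of their controls, and in 2 to the right.

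Of the 127 measured exons of target genes, 11% moved at least 10 points the same way in both lines, against 2.57% of the other exons, and 1 moved at least 10 points in opposite ways. The median smaller change over all 127 was 0 points, at percentile 48.0 of random exon sets, since many of these exons moved little or opposite ways; it was at percentile 99.4 when transcripts without a Cufflinks interval above 0 were left out. Over all 18004 exons, 72 moved at least 20 points the same way, against 14.0 expected of independent lists, and 73 moved opposite ways. Direction was therefore not shared more often than not. With a summed FPKM of at least 5, 5 exons moved the same way and 7 opposite ways. The largest smaller changes were in ZNF7 (80.5% and 38.6% in LCC2, 100% and 45.1% in LCC9), LGMN (99.99% and 61.7%, 67.4% and 0.00305%), USP21, MARK3, EBP, PDCD6, MIA2, TMEM116, NPIPB4 and WASF1. Of these 10 exons, those of PDCD6 and TMEM116 were higher and 8 were lower, and, MARK3 aside, most had a summed FPKM near the minimum of 1.

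Position on the chromosomes went with part of the knockdown ratios. In the LCC2 pair, the 145 genes on the short arm of chromosome 4 had a median of 0.55, the 302 genes beyond 68 Mb of the same chromosome -0.34 and the 172 genes of the distal long arm of X -0.47, against 0.08 over all 13086 eligible genes. In LCC9 the block medians were 0.07, -0.22 and -0.13, against -0.06. The limits of the blocks follow shifts in the window medians of the same LCC2 ratios. The LCC2 medians therefore describe the blocks and are no test of them. NPY1R, HPGD, SAP30 and SNX25 lie in the chromosome 4 block, which holds 2.31% of eligible genes and 6 of the 23 that were at least 2-fold lower in both lines. Those 23 genes were picked in part on the same LCC2 ratios. An excess of them in this block was therefore partly built in and is no test of it. After the median of each eligible gene's neighbourhood was subtracted, 112 of all tested genes differed at least 2-fold the same way, 83 higher and 29 lower. Tested genes that were not eligible had nothing subtracted.

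**Figure D5:**
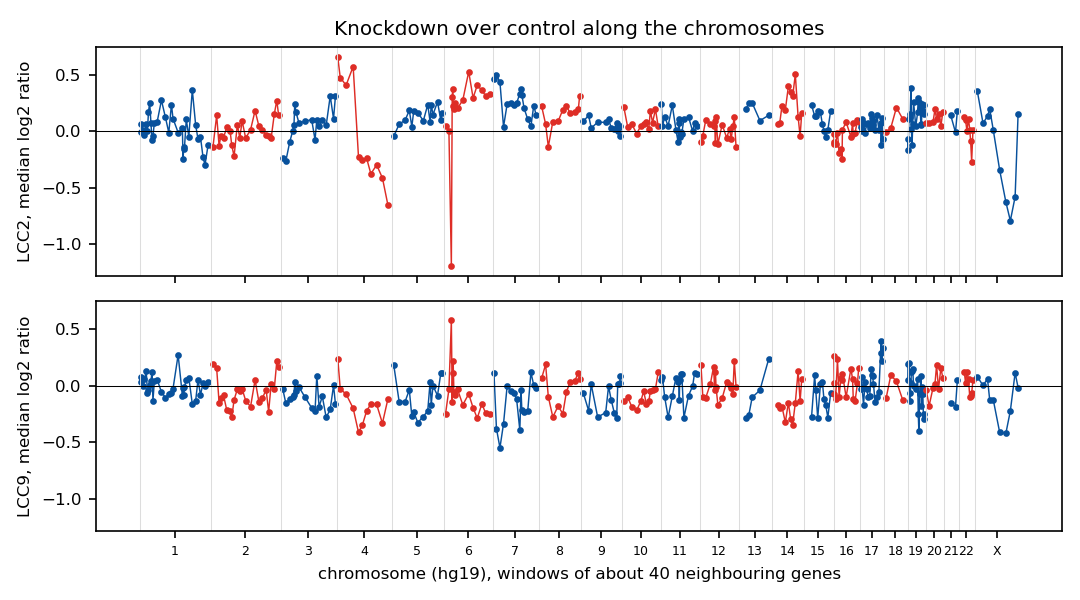
Median log2 ratio of knockdown over control in windows of about 40 neighbouring eligible genes along the hg19 chromosomes, for LCC2 (top) and LCC9 (bottom); colours alternate between chromosomes and each point is 1 window. Chromosome 4 changes sign along its length in LCC2, and the single low window on chromosome 6, which is high in LCC9, holds the histone gene cluster.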

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

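All results in this part were chosen because the knockdown ratio had opposite signs in the lines; with 1 library per group the difference itself was not tested. The tests of scaling, of swapped labels and of growth state were chosen after the results were seen. Differences are LCC9 minus LCC2 on the log2 scale.

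Higher in the LCC2 knockdown and lower in the LCC9 knockdown were the cytochrome P450 genes CYP1A1 (-5.73) and CYP1B1 (-4.30), both targets of the aryl hydrocarbon receptor, the stress cytokine gene GDF15 (-4.56), RPS27L (-3.69) and PRSS23 (-3.34). Lower in LCC2 and higher in LCC9 were the histone genes H1-5 (4.98), H1-3 (4.85), H3C13 (4.63) and H3C15 (4.0) and the centromere gene CENPU (4.29). Of the gene lists, those with opposite medians that lay outside the central 95% of random lists in both lines were replication histones (3.11), DNA replication (2.55), mitosis (2.03), p53 targets (-2.01), ATF4 stress (-1.64), glycolysis (0.82), hypoxia (0.49) and cholesterol synthesis (0.46).

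The cell cycle and p53 lists form 1 pattern: the LCC2 knockdown and the LCC9 control had low replication genes and high p53 targets beside the other pair of libraries. Over the 13086 eligible genes, this pairing held only for the LCC2 control and the LCC9 knockdown. The LCC2 knockdown and the LCC9 control were the least alike of all pairs. The SD of log2 differences was smallest between the LCC2 control and the LCC9 knockdown (0.528), below 0.569 within LCC2 and 0.614 within LCC9, and largest between the LCC9 control and the LCC2 control (0.755) or knockdown (0.761). A scaling difference is argued against, since 1 factor per library would move DNA replication and p53 targets the same way within a pair. They moved opposite ways in each pair. After median-of-ratios scaling all 4 medians of these lists kept their signs, with sizes of at least 0.92. The scaling factors lay between 0.908 and 1.10, too near 1 to turn medians of this size. Swapped labels in the LCC9 pair are argued against by ESRP1, which stood at 17.5% of the control in the LCC9 knockdown. Growth state of single cultures, such as confluence or medium age, and a line-specific effect of the knockdown cannot be told apart with 1 culture per group; the replication list of the LCC9 knockdown lay -0.48 from the LCC2 control after scaling, which may fit either.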

How the results depend on the processing

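Alternatives that leave out a library, replace the LCC9 control, subtract the neighbourhood median, keep the named genes of at least 300 nt, or apply to gene lists in LCC9 against LCC2 were chosen after seeing the data. Knockdown calls by limma (9) were 35 with pseudocount 0.1, 67 rescaled to a common sum, 0 with no filter (894 genes at unadjusted p under 0.05), 4 with median-of-ratios scaling, 4 with no term for line, and 4 among named genes of at least 300 nt. Leaving out the LCC2 control, LCC2 knockdown, LCC9 control or LCC9 knockdown gave 0 to 0 calls (1137, 211, 505 and 369 genes at unadjusted p under 0.05), with 3 libraries and no term for line, so that 2 choices changed at once. Calls between lines (35) were 96, 117, 0 (1605 genes at unadjusted p under 0.05), 10, 6 and 15 under the same settings, 18 with pseudocount 5, 22 with FPKM of at least 5 and again 0 to 0 without each library (912, 826, 672 and 2176 genes at unadjusted p under 0.05). Both main sets were contained in those with pseudocount 0.1. Rescaling moved the median difference between lines from 0.16 to 0.52. Of its calls, 46 of 67 rose with the knockdown and 76 of 117 were higher in LCC9. Genes 2-fold the same way (126) were 362 and 39 with pseudocounts 0.1 and 5, and 366 with the LCC2 control in place of the LCC9 control, where sharing a control builds in agreement, so that this setting says nothing on direction. Genes lower in LCC2 and higher in LCC9 (164) were 294, 93 and 10 under these settings, and those higher in LCC2 and lower in LCC9 (57) were 205, 13 and 6. Genes 2-fold in LCC2 (1266) were 2365 and 445, and in LCC9 (1511) 2639 and 594, with these pseudocounts. The 6 called lists were 0 with an estimated correlation; the ATF4 list mean was 0.37 in LCC2 alone, the only called list to turn its sign in a single line. Exons moving the same way (72) were 5 with summed FPKM of at least 5 (7 opposite), 474 at 10 points (566 opposite), 15 at 30 points (17 opposite) and 303 with the LCC2 control in place of the LCC9 control (9 opposite, against 73), again with a shared control. ESRP target exons lay at percentile 93.6 with summed FPKM of at least 5 and 99.4 with intervals above 0, against 48.0. Other settings kept each of these totals within 1.5 times. Counts by direction could move further, as the higher knockdown calls went from 6 to 3 with pseudocount 5. Under median-of-ratios scaling the ratios of AGR2, FGFR2 and VIM in LCC9 and of HMOX1 and ERN1 in LCC2, all small, changed sign. Nuclear oxidative phosphorylation genes, not called here, had been past the threshold under the earlier matching of older symbols, which was replaced after that result was seen. The cause of these shifts was not tested. The lower coverage per FPKM in LCC2 may limit low genes and exons more there than in LCC9, since depth sets their precision.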

Other observations

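The tests of shuffled positions, copy number, scaling, leukocyte markers and the vector, and the share of target exons, were chosen after the results were seen. The test of GC content and length was written down before; its first run also removed a trend with mean expression, and that term was then dropped to match the written test. Target exons moved the same way by at least 10 points more often than matched random exon sets: the share of 11% lay at percentile 100 of 10000 sets, whose median was 2.36% and central 95% ran from 0 to 5.51%. The random exons were drawn singly, whereas the 127 target exons come from 33 genes and share transcripts within a gene. The random range may therefore be too narrow. With summed FPKM of at least 5 the share was 13.4%, against 0.836% of the other exons.

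Neighbouring genes shifted together in the LCC2 pair. Chance arrangement is argued against, since the SD of window medians was 0.193, above the highest of 1000 shuffles (0.0974), although this SD also holds the histone cluster. GC content and transcript length are argued against, because 101% of the excess over the shuffles was kept after a fit on both, which itself removed 0.362% of the variance of the ratios. In the LCC9 pair the SD was 0.153, above the highest shuffle (0.107), and 73.7% of the excess was kept after a fit that removed 6.4% of the variance. A difference in DNA copy number between the control and knockdown cultures is a candidate explanation. Of the genes of chromosome 4 beyond 68 Mb, 72.8% were lower in the LCC2 knockdown, against 13.8% on its short arm and 43.3% of all eligible genes. The limits of these blocks follow the window medians of the same ratios. A high share was therefore built in by the choice and cannot decide on copy number. The explanation stays open because no DNA was measured. The labels also do not state whether the knockdown cultures were single clones, which could differ in copy number apart from ESRP1. The lower NPY1R, HPGD, SAP30 and SNX25 may in part go with a copy number difference. For NPY1R that part would be small if it had the size of the neighbourhood median. This median was -0.41 in LCC2 and -0.33 in LCC9, beside log2 ratios of -3.02 and -3.42 for NPY1R.

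Interferon genes were higher in both knockdown libraries. A scaling difference is argued against, since the lower of the medians in both lines was 0.60 after median-of-ratios scaling. Leukocyte RNA is argued against, since 0 of 12 blood cell markers reached an FPKM of 1 in both knockdowns and not in the controls; HBA1, the only 1 to reach it in a library, is a globin gene, not a leukocyte marker. A response to the knockdown vector, rather than to lower ESRP1, cannot be told apart from an effect of the knockdown, because ESRP1 was lowered by the same kind of vector in both lines; the median of 1.94 in LCC9 may come from either.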
